A study of Homo sapiens with 12 samples.

How the data were processed

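The study used eCLIP, a method in which RNA is crosslinked to protein by ultraviolet light, the protein is immunoprecipitated, and the bound RNA fragments are sequenced. The cells were HCT116, an established human colorectal carcinoma line. They were cultured for 48 h and crosslinked at 400 mJ/cm2, and an anti-FLAG antibody was used for immunoprecipitation, per the labels' protocols. Libraries were amplified with 11 to 15 PCR cycles and sequenced paired-end. The 12 samples fall into 6 groups of 2, an input and an immunoprecipitate (IP) for each of AGO2 knockout cells, cells with tagged wild-type AGO2 (FH-AGO2 WT) and cells with the tagged mutant FH-AGO2 5xA. Groups were taken from the sample titles.

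The 2 files used here are region lists, 1 for the WT IP and 1 for the 5xA IP. The sample descriptions give the same file for both IP replicates of a genotype, so each list pools its replicates. The deposited files have 6 columns and hold the chromosome, start, end, name, score and strand of each region. The deposited score column is 0 in every row, so it ranks nothing and no score was used. Coordinates are on hg38, and cutadapt 1.9.1 and TopHat2 are named, per the submitters' processing notes. The peak caller, its threshold, the use made of the input and knockout libraries and the rule that merged the replicates are not given in the sources used here. The other 8 samples (inputs and knockout IPs) were not analysed here. No read counts were used, so the depth behind each region is unknown, and neither a replicate error nor an interval for the number of regions could be given. Exact 95% Clopper-Pearson intervals are given for shares of regions. They and the tests on regions treat regions as independent draws, although some genes held many, and leave out the spread between cultures. Every p-value below compares these 2 lists and not the genotypes across replicates.

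Regions were shared when they overlapped by at least 1 base on the same strand, counted in Python and checked against bedtools 2.31.1. WT regions inside genes were placed at random 1000 times within the span of their own gene, and, as an addition, shifted by 200 to 1000 bases, to give the overlap that chance placement yields. Genes came from a RefSeq gene table of GRCh38.p14, whose chromosomes have the coordinates of hg38. It gives gene spans and biotypes but no strand, exon or sequence. A region was given to the protein-coding gene it overlapped, then to a lncRNA gene, then to any other gene, and to the shortest span among several. In the WT list 119 regions (10.0%) overlapped more than 1 gene, and in the 5xA list 319 (10.9%) did. Since the table has no strand, a region may come from an antisense neighbour. Each region was also given a class, with miRNA genes first, then other small RNA genes, protein-coding genes, lncRNA genes and pseudogenes. Regions on contigs outside chromosomes 1 to 22, X and Y kept their place in the counts but got no gene.

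Classes, gene list membership and positions were compared with two-sided Fisher's exact tests between disjoint sets, with Benjamini-Hochberg adjustment. Widths were compared by a two-sided permutation test of the medians with 100000 resamples. The 19 gene lists were written before the data were examined, as were the overlap rule, the counts of bound genes and the gene list tests. The planned rule named up to 10 genes each with most regions in both lists, in the 5xA list only and in the WT list only, all bound genes of the silencing machinery and AGO2 phosphorylation lists, up to 4 bound genes of each other list, and the 5 widest regions of each list. Ties went to the gene with more covered bases. Small RNA genes, lncRNA genes and single genes beyond this rule were chosen after their values were seen. The plan also held a split into 3' UTR, coding sequence and intron, miRNA seed matches, a scan of sequence words and a test of region scores. No genome sequence, exon annotation or score was used here, so these were not run. The substitutes were chosen after seeing the data: biotype classes for the classes of gene parts, placement in the whole gene span for placement in the same part of the gene, the distance to the downstream gene end for the 3' UTR class, and the region width for the score. Alternatives joined regions within 50 bases, counted regions within 50 bases of each other as shared, required a reciprocal overlap of 50%, ignored strand, took the class at the midpoint, left out contigs, changed the class order and the gene end window, left out regions overlapping more than 1 gene, and counted the near-identical snaR-A copies as 1 region. Gene tests were also run with only the regions within 5 kb of the downstream gene end. The settings from the contigs on were chosen after seeing the data, as were the joining of regions outside the region numbers and any alternative for gene end position and width. On simulated data with 300 planted shared regions, 301 were found. Of 200 random lists of 20 bound genes, 6.0% gave a p under 0.05 in the list test, and of 200 lists with 17 members planted in genes of both lists, 100.0% did. The planted lists had more bound genes than most lists tested here and were judged without adjustment. Their rate therefore does not carry over to the tests below. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.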

Results

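RNA bound by AGO2, the Argonaute protein that carries miRNAs to their target mRNAs, was mapped by eCLIP in HCT116 cells. The design compared wild-type AGO2 with 5xA, a form in which a cluster of phosphorylated residues is replaced by alanine, and asked which RNA sequences each form binds. The design also held AGO2 knockout cells, and how they entered the region lists is not given in the sources used here. The data compared here were 2 region lists, each merged by the authors from the 2 IP replicates of a genotype. The WT list held 1190 regions with a median width of 114 bases (quartiles 87 and 161), and the 5xA list held 2921 regions with a median width of 104 bases (quartiles 78 and 153). With 1 list per genotype there are no replicates to set the differences against, and the sequencing depth behind each list is unknown.

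The 5xA list was 2.45 times as long as the WT list and covered 405.4 kb against 172.4 kb, a ratio of 2.35. Of the 1190 WT regions, 967 (81.3%, 95% exact interval 78.9 to 83.4) overlapped a 5xA region, and 223 did not. Of the 2921 5xA regions, 944 (32.3%, 30.6 to 34.0) overlapped a WT region, and 1977 (67.7%) were found with 5xA only. More positions were shared than even placement in the same genes would give. Of 1127 WT regions inside genes, 926 overlapped a 5xA region, against 97.7 ± 7.75 (SD over 1000 placements, highest 131) when each was placed at random in its own gene (one-sided permutation test by random placement, p = 0.001, the smallest these placements can give). A shift of each region by 200 to 1000 bases left 253.3 ± 11.3 overlaps (permutation p = 0.001, the smallest possible). Neither placement kept regions to exons or to the downstream gene end, where most regions of both lists lay. Lists that share only such a preference would also exceed the placement in whole genes, and a shift may leave the exon or gene. The excess is therefore not a measure of shared binding sites alone.

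**Figure D1:**
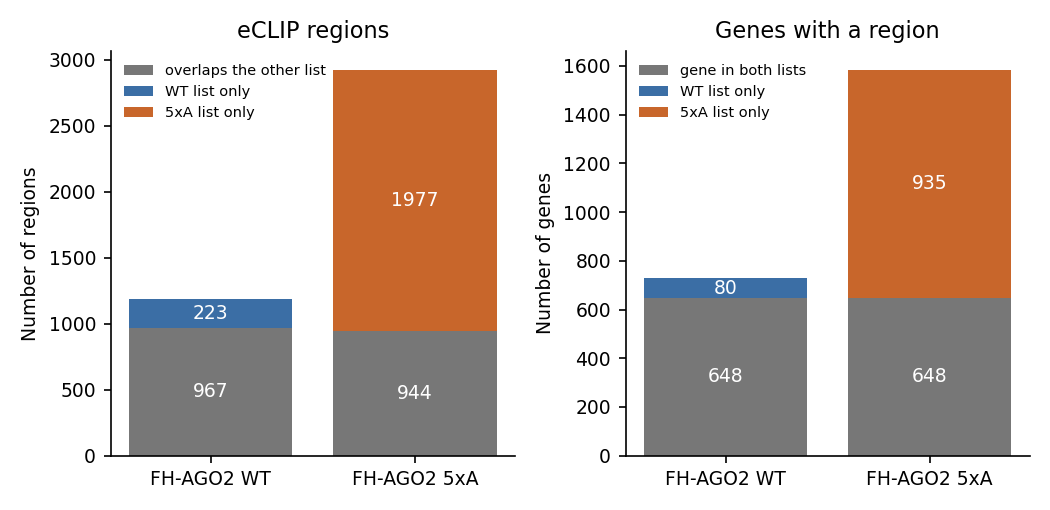
Number of eCLIP regions (left) and of genes with a region (right) in the merged FH-AGO2 WT and FH-AGO2 5xA lists, with 1 list per genotype and no error bars. Grey parts are shared with the other list (967 WT and 944 5xA regions, 648 genes) and coloured parts occur in 1 list only.

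The regions fell in 728 genes with WT and in 1583 genes with 5xA, 2.17 times as many. Of the WT genes 648 (89.0%) also held a 5xA region, 80 did not, and 935 genes held a region with 5xA only. Among protein-coding genes, 596 were in both lists, against 49.5 for independent lists drawn from all 20037 annotated protein-coding genes, a background that includes genes these cells do not express. Regions at a small RNA gene inside a protein-coding gene counted for the host, as at MIR7-1 in HNRNPK and MIRLET7F2 in HUWE1. Some hosts may thus be counted for the small RNA alone. In the 648 genes of both lists, 305 had more regions with 5xA, 36 had fewer and 307 had as many (two-sided exact sign test across genes, p = 3.03e-54; genes are not independent replicates, and a longer list gives more regions per gene by itself). Of 1900 5xA-only regions inside genes, 737 (38.8%, 36.6 to 41.0) lay in a gene that also held a WT region and 1163 lay in a gene without one. Of the 935 genes found with 5xA only, 758 held a single region.

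Among the genes in both lists, TET3 held the most regions. This gene, whose product oxidises 5-methylcytosine in DNA, held 10 WT and 17 5xA regions. ANKRD52, a subunit of the PP6 phosphatase complex that dephosphorylates AGO2, held 10 WT and 12 5xA regions. On hg38, all its regions lay between positions 56238107 and 56243087 of chromosome 12, in the downstream part of a gene that spans 56237807 to 56258384. MIDN and MKNK2, a kinase of the translation factor eIF4E, each held 9 WT and 10 5xA regions. HIC2, a transcriptional repressor, held 9 in each list. The Polycomb protein gene CBX6 held 4 WT and 14 5xA regions, and each of the 4 WT regions was shared. The H3K27 demethylase gene KDM6B held 7 WT and 9 5xA regions. ZC3HAV1L held 7 and 11, NACC1 held 6 and 10, and NACC2 held 6 and 9.

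The genes found with 5xA only were led by ZNF385A with 5 regions. MEX3D, which encodes an RNA-binding protein, PIAS4, a SUMO ligase, the p53-induced nuclease gene AEN, ZC3H4, the lncRNA gene LINC02604, the transcription factor gene CUX1, the scaffold gene AKAP12 and the casein kinase gene CSNK1E held 4 each, and ZNF680 held 3. All regions of ZNF385A also lay in the span of GPR84-AS1, and those of CSNK1E in that of the readthrough gene TPTEP2-CSNK1E. All 80 genes found with WT only held 1 region. By covered bases these were led by the pyruvate kinase gene PKM, HES6 (173 bases), the p53 target PERP (167 bases) and the ERK phosphatase gene DUSP6 (166 bases). They were followed by PES1, H3-7, HSPA1B, REPIN1, TMEM250 and DENND5B-AS1. The DUSP6, H3-7 and REPIN1 regions also lay in the span of another gene. HSPA1B has a near-identical copy, so its reads may be split.

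Genes of the miRNA silencing machinery were among those bound. Of 42 members, 7 held regions in both lists, 3 with 5xA only and 0 with WT only. TNRC6A, which encodes a GW182 scaffold protein that recruits the deadenylases to AGO, held 5 WT and 9 5xA regions, and its paralogs TNRC6C and TNRC6B held 3 and 6, and 1 and 3. DICER1, the nuclease that cuts miRNA precursors, held 4 and 8. DDX6 held 2 and 1, and AGO4 held 1 in each list. PABPC1 (2 regions), LSM14A (1 region) and CNOT4 (1 region) were found with 5xA only, and 1 of the PABPC1 regions also covers MIR7705. The AGO2 gene itself held 3 regions in each list. The WT regions lay at positions 140520949 to 140521121, 140521132 to 140521241 and 140522206 to 140522363 of chromosome 8, all on the minus strand and 879 to 2128 bases from the downstream gene end. The 5xA regions began at 140520792, 140522246 and 140531016, and the first and second overlapped WT regions. Values of AGO2 per library were not analysed here, so the knockout could not be checked. In the AGO2 phosphorylation list, 9 of 11 genes held no region. Beside ANKRD52, CSNK1E held 4 regions with 5xA and none with WT.

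Reported targets of let-7, a miRNA family that represses growth genes, were bound with both forms. Of 33 let-7 targets, 13 held regions in both lists and 4 with 5xA only. HIC2 held 9 and 9 WT and 5xA regions, DICER1 4 and 8, the cyclin gene CCND1 5 and 6, and HMGA2 5 and 5. The regions of HMGA2, the gene of a chromatin protein, covered 3811 bases with WT and 3967 bases with 5xA. In each list 4 of its regions lay within 2974 bases of the downstream gene end, and 1 lay at the upstream end, where RPSAP52 also lies, from position 65824385 (WT) and 65824381 (5xA) of chromosome 12. Of 32 reported targets of the miR-17 family, 9 were in both lists, 5 with 5xA only and 1 with WT only. They included the transcription factor gene E2F3 (7 WT and 5 5xA regions), the CDK inhibitor gene CDKN1A (6 and 4) and TP53INP1 (2 and 7), whose regions all lay in the span of NDUFAF6 too. In E2F3 and CDKN1A the fewer 5xA regions covered more bases, 1120 against 1020 with WT and 1349 against 1049. In CDKN1A 1 5xA region, from 36685912 to 36686689 on chromosome 6, spanned several WT regions. Of 21 reported miR-21 targets, 4 were in both lists, 2 with 5xA only and 1 with WT only, among them BTG2 (6 and 7), RHOB (3 and 6), YOD1 (3 and 5) and the phosphatase gene CDC25A (1 and 4). The YOD1 regions all lay in the span of PFKFB2 too.

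Of 25 p53 pathway genes, 9 were in both lists and 2 with 5xA only. BTG2 and CDKN1A were joined here by the p53 ligase gene MDM2 (5 WT and 8 5xA regions). Of 36 cell cycle genes, 10 were in both lists and 3 with 5xA only, with CDKN1B at 3 regions in each. In the BCL2 family list, 4 of 21 genes were in both lists and 1 with 5xA only. BBC3 held 4 and 3 regions (514 and 749 bases), MCL1 3 and 4, BCL2L11 2 and 4 and PMAIP1 1 and 2. Of 34 TGF-beta and BMP genes, 6 were in both lists, 2 with 5xA only and 1 with WT only. The SMAD corepressor gene SKI held 4 and 11 regions, TGIF1 2 and 2, and BMP4 and ACVR2B 1 and 2 each. Of 37 Wnt genes, 5 were in both lists and 4 with 5xA only. TCF7L2 and BCL9L held 1 and 3 regions each, DKK1 2 and 1 (580 and 547 bases), and TCF7L1 1 and 2. Of 44 PI3K and RAS genes, 4 were in both lists, 7 with 5xA only and 2 with WT only. SPRY4 held 7 and 6 regions (1146 and 1264 bases), DUSP5 3 and 5, TSC2 3 and 4, and IRS1 0 and 3. All TSC2 regions also lay in the span of PKD1 and at least 40884 bases from the downstream end of TSC2 on their strand. They were given to TSC2 for its shorter span only and may come from PKD1. The place of TSC2 among the genes in both lists is therefore uncertain. Of 25 epithelial-mesenchymal transition genes, 2 were in both lists, 4 with 5xA only and 1 with WT only, with ITGB1 and CFL2 at 1 and 2 regions each.

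Abundant mRNAs and markers of other cell types were measured beside these lists. Of 32 housekeeping genes, 3 were in both lists, 6 with 5xA only and 1 with WT only, with FTL at 1 and 3 regions and YWHAZ at 0 and 3. Of 86 ribosomal protein genes, 2 were in both lists and 5 with 5xA only, and of 63 replication-dependent histone genes, 3 and 8. Of 509 ZNF genes, 10 were in both lists, 17 with 5xA only and 1 with WT only. Of 18 colorectal epithelial markers, CLDN4 held 2 WT regions (716 bases) and 1 5xA region (835 bases) that spanned both. VIL1 held 1 with 5xA only, in a place that USP37 also spans. Of 14 fibroblast markers, COL1A1 held 2 and 4 regions, and COL6A1 and COL6A2 held 1 each with 5xA only. Of 15 blood cell markers, 0 held a region.

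Between the 935 genes found with 5xA only and the 648 genes in both lists, 0 of the 18 gene lists with a bound member differed after Benjamini-Hochberg adjustment (two-sided Fisher's exact tests). At an unadjusted p under 0.05, 3 lists made up a smaller share of the genes found with 5xA only. By Fisher's exact test they were the let-7 targets (odds ratio 0.21, 95% interval 0.0497 to 0.684, p = 0.00467), the p53 pathway (0.15, 0.0160 to 0.740, p = 0.00992) and the cell cycle (0.21, 0.0362 to 0.802, p = 0.0102), each with an adjusted p of 0.0613. These lists share members such as CDKN1A and CCND1. With only the regions that overlap a single gene, the let-7 and cell cycle lists passed, each with an adjusted p of 0.0494 (exact tests). With only the regions within 5 kb of the downstream gene end, the let-7 list passed, at an adjusted p of 0.0288 (exact test), and the cell cycle list did not, at 0.177.

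**Figure D2:**
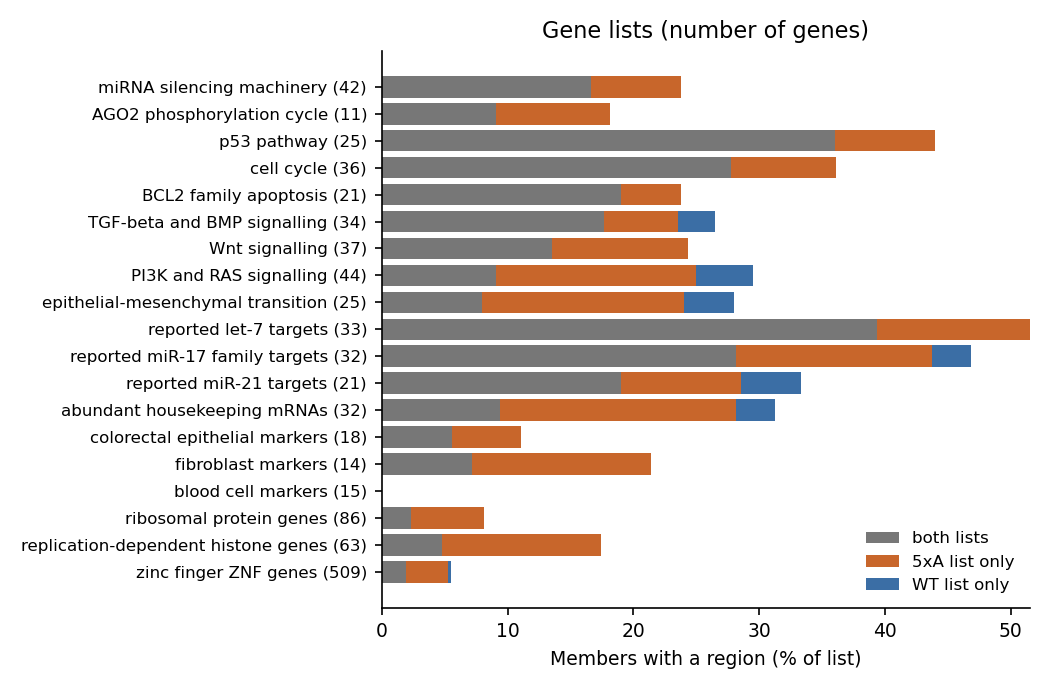
Share of the members of each gene list (x axis, percent; number of genes in parentheses) that held a region in both lists (grey), with 5xA only (orange) or with WT only (blue). The let-7 target list has 13 of 33 members in both lists and 4 with 5xA only, and no blood cell marker held a region.

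Most regions lay in protein-coding genes, 87.7% (85.7 to 89.5) of the WT list and 90.0% (88.8 to 91.0) of the 5xA list. miRNA genes held 21 WT and 33 5xA regions. All 21 miRNA genes of the WT list were also in the 5xA list. They included the let-7 genes MIRLET7A1, MIRLET7A2, MIRLET7A3, MIRLET7B, MIRLET7F2 and MIRLET7I, of which several encode the same mature miRNA, and MIR21, MIR16-1, MIR18A, MIR93, MIR106B, MIR34A, MIR181A1 and MIR7-1. A further 13 miRNA genes were in the 5xA list only, among them MIR182, MIR96 and MIR183, which lie together on chromosome 7, and MIR191, MIRLET7F1 and MIRLET7G. Not all of these regions lay squarely on the miRNA gene. The MIR10399 region met its gene by 1 base and the MIR4658 region by 29 of 65 bases, and the MIR7705 region was 402 bases wide, while in both lists the regions at MIR4721 and MIR614 lay mostly outside the gene. Regions at miRNA genes had a median width of 66 bases in both lists. Other small RNA genes were also in both lists, including 13 copies of the snaR-A family, 4 vault RNA genes and RNY4. The snaR-A copies are near-identical, and how their reads were divided is not given in the sources used here.

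Among 5xA regions, those found with 5xA only touched miRNA genes less often than the shared ones did. The shares were 0.658% (13 of 1977) and 2.12% (20 of 944), an odds ratio of 0.31 (95% interval 0.139 to 0.650, two-sided Fisher's exact test, adjusted p = 0.00623). Other small RNA genes made up 0.759% (15 of 1977) and 2.22% (21 of 944), an odds ratio of 0.34 (0.160 to 0.688, exact test, adjusted p = 0.00623). Of the shared ones 13 were snaR-A copies, and with these counted as 1 region no difference was detectable (odds ratio 0.73, exact test, adjusted p = 0.782). Of 15 regions at tRNA or snoRNA genes, 12 were found with 5xA only, beside 67.7% of all 5xA regions, and this was not tested. When regions in a miRNA gene inside a protein-coding gene were classed as protein-coding, fewer miRNA regions were left, and the miRNA odds ratio was 0.34 with an adjusted p of 0.173 (exact test, against 0.00267 to 0.00705 in the other alternatives). Protein-coding genes took 90.9% of 5xA-only and 88.0% of shared regions (exact test, adjusted p = 0.0413), a call that 5 of 6 alternatives ended. lncRNA genes, pseudogenes, sites outside annotated genes and contigs did not differ detectably. In the WT list 0 of 223 WT-only regions touched a miRNA gene, which allows a share of up to 1.64% (exact 95% upper bound), against 21 of 967 shared regions (adjusted p = 0.0516).

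Regions lay near the downstream end of genes, the side where 3' UTRs are. In protein-coding genes longer than 10 kb, and reading the gene in the direction of the region's strand, 79.0% (76.1 to 81.8) of 840 WT regions and 77.7% (75.9 to 79.5) of 2128 5xA regions lay within 5 kb of the downstream gene end. An even spread over these genes would give 17.5% and 16.4%. The upstream 5 kb held 4.05% and 4.79%. In the WT list the share was lower for WT-only than for shared regions, at 68.0% (104 of 153) against 81.5% (560 of 687), with an adjusted p of 0.000792 over both lists (two-sided Fisher's exact test). In the 5xA list it was 76.5% (1114 of 1456) for 5xA-only and 80.4% (540 of 672) for shared regions (exact test, adjusted p = 0.0498). Requiring a reciprocal overlap of 50% ended both calls, and a 10 kb window ended the one in the 5xA list (exact test, p = 0.669). These tests counted each region as independent, although genes such as ANKRD52 and HIC2 held many.

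**Figure D3:**
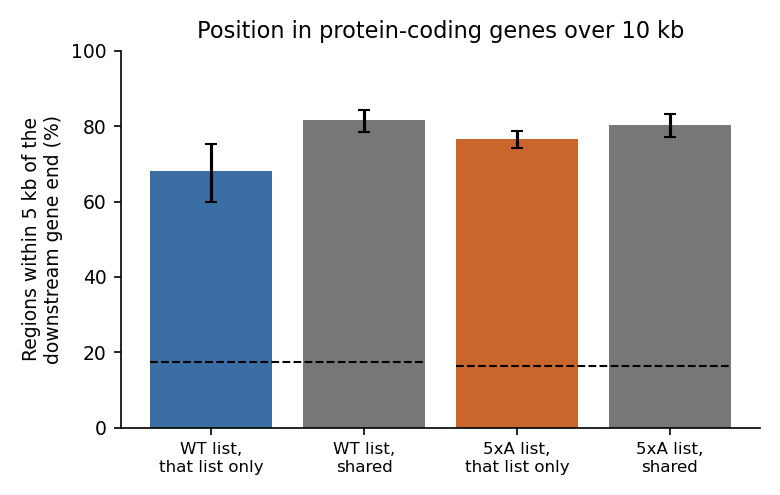
Share of regions (y axis, percent) within 5 kb of the downstream gene end in protein-coding genes longer than 10 kb, for regions in 1 list only (blue and orange) and shared regions (grey); error bars are exact 95% intervals and dashed lines the shares of an even spread (17.5% and 16.4%). All bars lie between 68.0% and 81.5%, far above the dashed lines.

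Regions found in 1 list only were narrower than shared ones. In the 5xA list the median width was 93 bases for 5xA-only and 145 bases for shared regions, and in the WT list 91 and 121 bases (two-sided permutation tests of the medians, p = 1e-05 each, the smallest that 100000 resamples can give). A wider region meets the overlap rule more easily, whatever its strength. In 847 pairs of regions that overlapped one another alone, the 5xA region was the wider in 566 and the WT region in 257 (two-sided exact sign test across pairs, p = 1.65e-27), with a median difference of 14 bases. Pairs are not independent replicates. With 1 list per genotype, a difference in width cannot be told apart from differences in depth, threshold or merging. The widest WT regions were in ZFP36 (1508 bases), the gene of an mRNA-destabilising protein, EREG (1157 bases), ZFP36L1 (1067 bases) and HMGA2 (1010 and 997 bases). The widest 5xA region spanned 6057 bases across 4 tRNA genes and HES7, from 8119763 to 8125819 on chromosome 17. It was followed by regions in HMGA2 (2009 bases), the pseudogene AFG3L1P (1626 bases), CSTB (1605 bases) and ZFP36 (1521 bases).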

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

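Except for the joining of regions within 50 bases, the tests in this part were chosen after the result was seen. Regions on contigs outside the chromosomes were kept in the region counts and formed a class of their own, but entered no gene comparison. There were 36 in the WT list (3.03% of its regions), of which 21 were on alternate versions of chromosome 6, and 59 in the 5xA list (2.02%), of which 32 were. In each list 24 of them overlapped the other.

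The first pattern was the greater length of the 5xA list. Finer splitting of regions is argued against, since joining regions within 50 bases left a ratio of 2.42. Housekeeping, ribosomal protein, histone and other small RNA genes held 1.97% of the 5xA-only regions (95% interval 1.41 to 2.69). Regions in them thus make up little of the added length, but so few and mostly short genes could hardly hold more. Bound housekeeping genes numbered 4 with WT and 9 with 5xA, ribosomal protein genes 2 and 7, and histone genes 3 and 11. All bound genes numbered 728 and 1583. Whether abundant background RNA added regions is therefore left open, and RNA of other genes was not covered by this test. Greater depth or a looser threshold for 5xA and a wider binding by the mutant cannot be told apart from the lists. With depth alone few WT regions would be missing from the longer list, and 18.7% were, but no read counts, scores or separate replicates were used that would say how many chance leaves out.

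The second pattern was the set of WT regions with no 5xA partner. Few of these 223 regions just missed an overlap, since 8.97% (95% interval 5.56 to 13.5) lay within 50 bases of a 5xA region. Sites whose ends shifted less had already been counted as shared. The overlap rule thus largely set this low share, and it does not decide on shifted ends. Of 201 WT-only regions inside genes, 123 (61.2%, 54.1 to 68.0) lay in a gene that also held a 5xA region, and 49.3% of all 223 lay within 1000 bases of one. Weak regions near the calling threshold and a loss of these sites by the 5xA protein cannot be told apart from the lists. The shared WT regions were wider by 30 bases in the median, but a wider region overlaps another more easily whatever its strength, so this width decides nothing.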

How the results depend on the processing

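No paired analysis was possible because each list merges the replicates of its genotype, so no replicate number reaches the data, and no replicate could be left out. Of 138 alternative values, 105 kept their direction and side of the threshold or, for counts, stayed within 1.5 times, 23 were weaker, 4 stronger, 2 moved and 4 changed direction. These 4 were odds ratios past the threshold in neither setting: lncRNA genes at 0.97 (5xA list) and 0.95 (WT list) and protein-coding genes in the WT list at 1.30 with the reciprocal overlap, and the latter at 1.01 on chromosomes only. In the gene list tests, only the let-7, p53 and cell cycle lists were followed singly. Comparisons with abundant mRNAs were followed only where the main test had passed, so those that failed could not count as stronger. The ratio of region numbers ranged from 2.42 to 2.48 and the number of shared WT regions from 797 (reciprocal overlap of 50%) to 987 (within 50 bases). For 5xA-only against shared regions, the odds ratio for miRNA genes was 0.34 and no longer significant with protein-coding genes classed first, and that for other small RNA genes was 0.73 and no longer significant with the snaR-A copies counted as 1 region, since 13 of the 21 shared ones were such copies. That for protein-coding genes missed the threshold at 1.34 with the class at the midpoint, 1.27 with protein-coding genes first, 1.33 on chromosomes only, 1.36 with joined regions and 1.22 with the snaR-A copies as 1 region. For WT-only regions the odds ratio for other small RNA genes, 0 in all settings, passed (exact test, adjusted p = 0.00305, against 0.0516 to 0.426 in the others) with the reciprocal overlap. The gene end odds ratio lost significance at 0.86 (5xA list) and 0.91 (WT list) with the reciprocal overlap and at 0.93 (5xA list) with a 10 kb window. In the gene list tests, 2 lists passed with regions overlapping 1 gene only, the let-7 targets at an odds ratio of 0.22 and the cell cycle at 0.14, and 1 list passed near gene ends, the let-7 targets at 0.16. The cause of the other changes was not tested. Protein-coding genes first, chromosomes only, snaR-A copies as 1 region, joined regions outside the region numbers, all gene end and width settings and both gene list settings were chosen after the data were seen. Settings with scores, 3' UTRs, coding sequence, seed types and sequence words, chosen earlier, were not run. Unknown depth limits every statement on regions missing from a list.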

Other observations

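The tests in this part were chosen after the data were seen. Several lncRNA genes held regions. NORAD, a cytoplasmic RNA that binds Pumilio proteins, held 4 WT and 9 5xA regions, LINC01061 2 and 7, OIP5-AS1 3 and 4, and SNHG16 0 and 3, of which 1 lay within the snoRNA gene SNORD1A. Among 5xA regions at small RNAs other than miRNAs, tRNA or snoRNA genes were touched by 15, of which 12 were found with 5xA only, while snaR-A, vault or Y RNA genes were touched by 20, of which 2 were found with 5xA only. These families were grouped after seeing which were shared, and 14 of the 20 regions are near-identical snaR-A copies, so no test is given. Regions touching tRNA genes numbered 2 with WT and 11 with 5xA, of which 2 wide ones spanned 6 of the 15 tRNA genes met, and those touching snoRNA genes 0 and 4. One of these 4, at SNORA86 on chromosome 10, met the gene by 28 bases only and was shared. The WT region overlapping it began at position 32901476, just past the last gene position, 32901472. Knockout regions, which would show the background at these genes, were not analysed here.

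Genes of the ZBTB family, transcription factors with a BTB domain and zinc fingers, stood out among the genes with many regions. ZBTB20 held 3 WT and 11 5xA regions, ZBTB34 3 and 10, ZBTB7B 3 and 8 and ZBTB7A 3 and 7. In the WT list 7 of 41 ZBTB and 11 of 509 ZNF genes held a region (odds ratio 9.24), and in the 5xA list 10 and 27 did. The family was picked because its members were bound, so this odds ratio restates the observation, and whether ZBTB genes are bound more often than ZNF genes stays open. Expression and 3' UTR length were not measured and may differ between the families.

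Bound shares were also set against 118 abundant mRNAs (housekeeping and ribosomal protein genes), of which 6 held a WT region. The let-7 targets were bound more often, 13 of 33 (odds ratio 11.8, 95% interval 3.69 to 42.7, adjusted p over 34 tests 0.000109). The p53 pathway (9 of 25), miR-17 family targets (10 of 32) and cell cycle genes (10 of 36) also were (exact tests, adjusted p = 0.00109, 0.00147 and 0.00304), and with 5xA the adjusted p was 0.000252 for the let-7 targets, and 0.00585, 0.00403 and 0.0227 for these lists (exact tests). TGF-beta and BMP genes (7 of 34) and miR-21 targets (5 of 21) passed with WT (exact tests, adjusted p = 0.0331 and 0.0383) but not with 5xA (8 of 34 and 6 of 21, adjusted p = 0.284 and 0.216). The miRNA silencing machinery passed with neither form (7 of 42 with WT and 10 of 42 with 5xA, exact tests, adjusted p = 0.117 and 0.247). Apart from the ZNF genes, no other list passed with either form. With only the regions near gene ends, the TGF-beta call with WT (odds ratio 3.85 against 4.77, exact test, adjusted p = 0.118) and the p53 call with 5xA (3.82 against 4.93, adjusted p = 0.05003) ended. With only the regions overlapping 1 gene, the miR-21 call with WT ended (4.32 against 5.72, exact test, adjusted p = 0.117). Against the 32 housekeeping genes alone, a smaller reference, none of these calls held, with an odds ratio of 4.44 and an adjusted p of 0.257 for the let-7 targets (exact test). The odds ratios fell too, for the p53 pathway with WT from 10.2 to 3.84. With WT 4 of 32 housekeeping and 2 of 86 ribosomal protein genes were bound. The calls thus rested largely on the ribosomal protein genes. Against the housekeeping genes alone the odds ratios of these lists still lay above 1, and 32 genes are few. Whether these lists were bound more often than abundant mRNAs in general therefore stays open. ZNF genes were bound less often than the abundant mRNAs with 5xA, 27 of 509 against 16 of 118 (odds ratio 0.36, exact test, adjusted p = 0.0155), and this call held against the housekeeping genes alone (0.14, adjusted p = 0.00295) and with both region settings (adjusted p = 0.0222 and 0.00243). With WT 11 of 509 ZNF genes were bound, which did not pass (odds ratio 0.41, exact test, adjusted p = 0.216). The median gene span was 50.2 kb for the let-7 targets and 5.09 kb for the ribosomal protein genes, and length may contribute.

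Chromosome 19 held 13.5% of WT and 11.4% of 5xA regions and 7.24% of the annotated protein-coding genes. Across 23 chromosomes, 0 differed in their share of 5xA-only and shared regions after Benjamini-Hochberg adjustment (Fisher's exact tests), with 4 at an unadjusted p under 0.05.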
